A study of Mus musculus with 8 samples.

How the data were processed

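RNA from mouse hearts was extracted with Trizol and made into libraries from 1 microgram of total RNA with the NEBNext Ultra RNA Library Prep Kit, per the labels. The submitters' notes name CASAVA 1.8, Bowtie 0.12.2, featureCounts 1.5.0-p3 and the builds mm8 and mm10, with no role or order. The strand setting, filters and scaling method are not stated. Of the 54495 gene identifiers shared with GENCODE release 21 for mouse (GRCm38, which mm10 is another name of), 53585 had the same chromosome, start and end in the deposited table.

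The authors deposited 1 table of 54532 genes and 8 libraries, named as counts, whose values are FPKM. Each value times the listed gene length was a whole multiple of 1 step per library, within 0.01 of a read for 100% of values above 0. The steps give the reads per gene and a library size that was 0.886 to 1.10 times the total of the reads and followed median-of-ratios factors within 0.796%. The deposited FPKM thus rest on a library size scaled between samples. The recovered reads summed to 16038971 and 15574769 in WT sham, 17057869 and 17313084 in WT TAC, 16865275 and 16202258 in Cko sham, and 16734502 and 16523039 in Cko TAC. Mitochondrial genes took 17.6% to 24.4% of them.

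The design fixed before the data were examined assumed raw counts and a count model, edgeR, which was not used because the values are FPKM. limma 3.58.1 in R 4.3.3 was used in its place, and DESeq2 was not run. The values were log2(FPKM + 0.5), kept for genes with at least 0.5 FPKM and 10 recovered reads in at least 2 libraries. A linear model with 1 term per group was fitted to all 8 libraries (4 residual degrees of freedom, median prior degrees of freedom 3.54) with an intensity trend and robust variance moderation. Samples were grouped by the genotype and surgery the labels give. The 5 comparisons were TAC against sham in each genotype, Piezo1-Cko against wild type under each surgery, and the interaction, the Piezo1-Cko response minus the wild-type response. Adjusted p-values are Benjamini-Hochberg over the 13928 tested genes of a comparison, two-sided, with a threshold of 0.05. The libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom of 17.3 to 44.2, so none was a copy of another.

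Gene lists for 32 pathways and cell types were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, with a correlation estimated per list and fry as alternatives. A symbol shared by 2 gene identifiers enters a list once, at the row with the higher mean. That rule was set after list results had been seen; it left the number of lists passing camera in each comparison as it was and changed the number passing fry in wild type from 3 to 4. A further list of sex-linked genes served as a check: Ddx3y was at 9.84 to 16.8 FPKM and Xist at most 0.0196 in all 8 libraries.

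Named genes follow a rule fixed before the data were examined. It takes Piezo1 in each comparison and 12 textbook genes of pressure overload in both TAC comparisons. It takes the 6 largest rises and 6 largest falls that passed, with a mean log2 CPM of at least 1 and libraries that did not overlap (the interaction has no overlap rule), leaving out predicted genes and pseudogenes. For each list that passed, it takes the 3 members with the smallest p in its direction and the member in the other direction with the smallest p, if that passed. Where under 3 genes passed, the 3 with the smallest p are named as not passing. The text takes examples from each set.

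The steps were tested on simulated data, 10 draws of negative binomial reads with the libraries' sizes and 200 genes changed in WT TAC, 100 of them 2-fold and 100 of them 4-fold. For TAC against sham in wild type, 54.8% of the former and 85.6% of the latter were recovered, with 12.9 unchanged genes passing per draw, a share of the calls above the 0.05 threshold. For the interaction the shares were 17.1% and 69.7%, with 10.1 unchanged genes passing. Of 10 simulated lists of 30 genes raised 1.5-fold, camera found 10, and it called 1 of 10 unchanged lists at an unadjusted 0.05. The simulation drew genes independently, while correlations estimated within the lists ran from -0.259 to 0.925.

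Alternatives were median-of-ratios scaling, limma-voom on the recovered reads, other filters, protein-coding genes alone, mitochondrial genes left out of the scaling, the 4 libraries compared alone, the replicate number as a block, each library left out in turn and a fold-change threshold. Chosen after seeing the data were pseudocounts of 0.1 and 1 FPKM, trimmed-mean scaling, a clock gene index as a covariate, every row of a shared symbol kept in lists, and leaving out both libraries that stand apart. Pseudogene copies were found by aligning GENCODE processed pseudogene transcripts to protein-coding transcripts with minimap2 2.31-r1302 (at least 90% identity over at least 50% of the copy). Exact intervals on shares of genes are binomial over genes.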

Results

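RNA was sequenced from mouse heart tissue (strain C57BL/6 per the labels) in 4 groups of 2 libraries each. The groups crossed genotype, wild type or Piezo1-Cko, with surgery, sham or TAC. TAC is the usual abbreviation of transverse aortic constriction, a narrowing of the aorta that loads the left ventricle with pressure; sham surgery omits the narrowing. Piezo1 encodes a mechanically activated cation channel. The labels do not say which cells or exons the Piezo1-Cko allele affects. The deposited FPKM values (fragments per kilobase of gene, scaled to library size) were turned back into whole reads, which summed to between 15574769 in WT sham replicate 2 and 17313084 in WT TAC replicate 2. Of 54532 listed genes, 13928 passed the filter on low values and were tested. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values, and adjusted p-values are from limma with Benjamini-Hochberg adjustment. Genes named as risen, fallen, higher or lower had both libraries of 1 group beyond both of the other, which the naming rule required of the largest changes.

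The targeted gene was read first in every library. Piezo1 (ENSMUSG00000014444, GRCm38 chromosome 8, 122481698 to 122551329, minus strand) was not detectably lower in the libraries labelled Piezo1-Cko. Under sham it was at 2.72 ± 0.525 FPKM (SD, n = 2) in wild type and 3.53 ± 0.421 in Piezo1-Cko, a log2 fold change of 0.33 (SE 0.186, adjusted p = 0.774). Under TAC it was at 5.61 ± 0.318 FPKM in wild type and 4.57 ± 0.954 in Piezo1-Cko, a log2 fold change of -0.28 (SE 0.186, adjusted p = 0.652). The reads behind these values were 332 and 436 in WT sham, 995 and 1023 in WT TAC, 583 and 492 in Cko sham, and 960 and 668 in Cko TAC. A gene total keeps reads of exons outside a deleted part and of cells in which the allele is intact. The gene's span also overlaps Ctu2, Gm26497 and Gm20388, and the strand setting of the counting is not stated, so this total does not check the genotype labels.

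**Figure D1:**
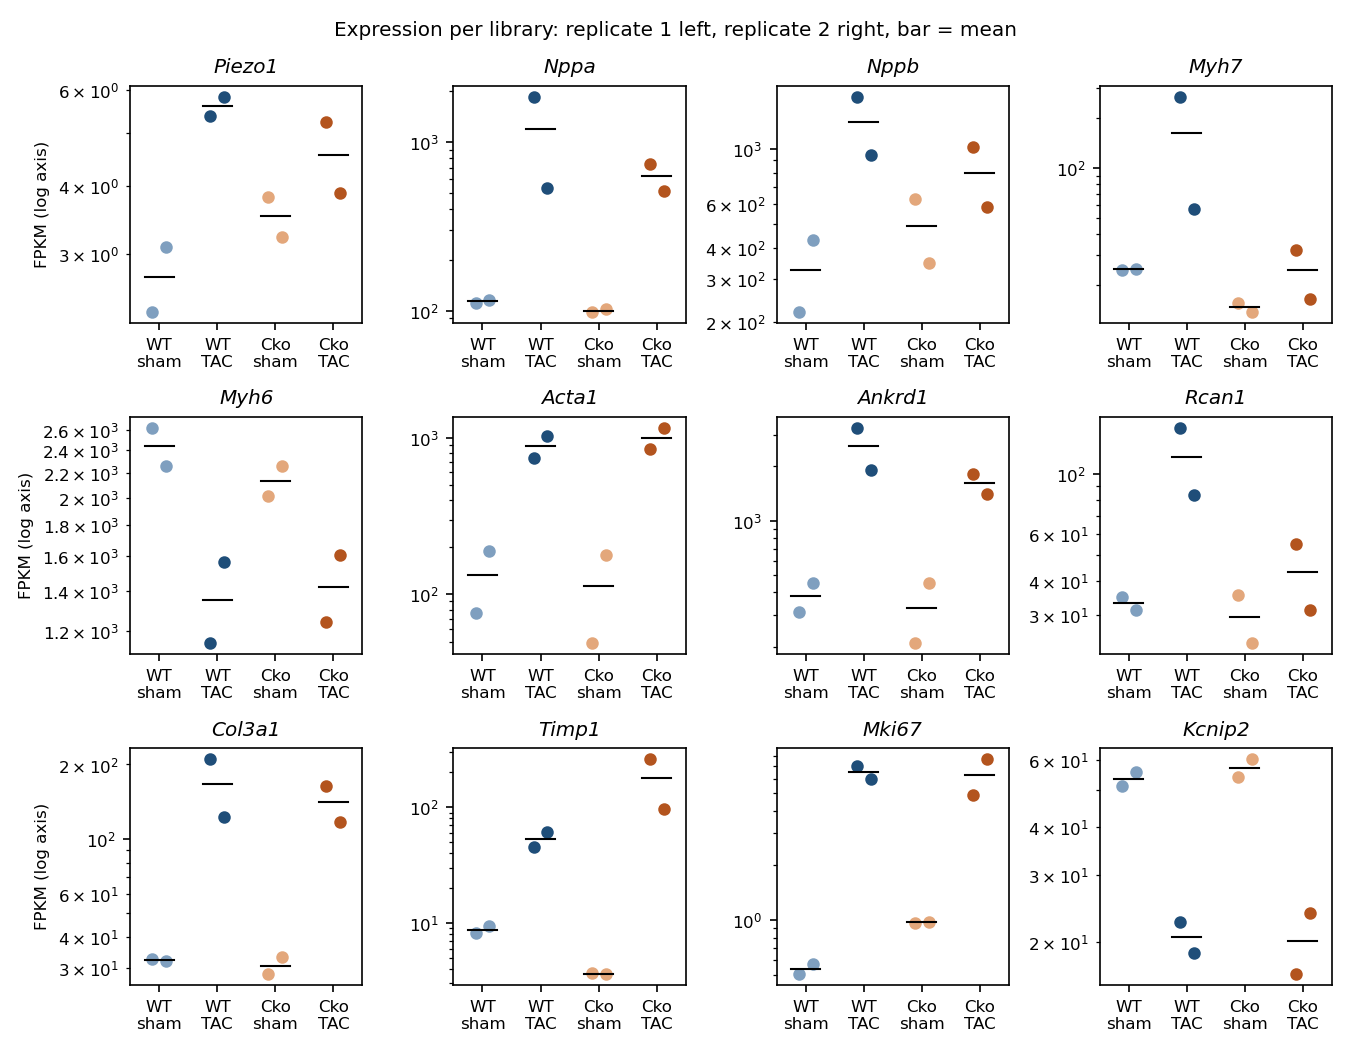
FPKM on log axes (the range differs between panels) of 12 genes in each of the 8 libraries, with replicate 1 to the left and replicate 2 to the right within a group and a bar at the group mean. Nppa, Ankrd1, Col3a1, Timp1 and Mki67 were higher and Kcnip2 lower in all 4 TAC libraries than in all 4 sham libraries, while Piezo1 in the Cko libraries lay between 3.24 and 5.24 FPKM.

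TAC was compared with sham in wild type to ask what the surgery changed there. Cell cycle and extracellular matrix genes rose as lists, and nuclear genes of mitochondrial energy production fell as a list (each adjusted p = 0.561 with an estimated correlation). Mki67, a marker of dividing cells, rose 6.73-fold from 0.539 ± 0.0502 to 6.50 ± 0.717 FPKM (SD, n = 2; log2 fold change 2.75, SE 0.210, adjusted p = 0.00573). Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079, overlapping Gm13054), rose 8.70-fold from 114 ± 3.03 to 1193 ± 935 FPKM (adjusted p = 0.0177). In all, 776 genes were higher and 1066 lower, and 4689 genes had an unadjusted p under 0.05. Mki67 passed whichever library was left out, and Nppa lost its call without WT sham replicate 1 or 2 (adjusted p up to 0.0756). The log2 fold change of Nppa was 2.22 without WT TAC replicate 1 and 4.02 without WT TAC replicate 2.

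Of the 26 measured cell cycle genes, 24 rose over all genes tested and 25 adjusted over the list alone, with a median log2 fold change of 2.04 (camera adjusted p = 1.58e-20; adjusted p = 0.561 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose 6.51-fold, Cks2 9.90-fold, Rrm2, a subunit of ribonucleotide reductase, 9.47-fold and Ube2c, a ubiquitin-conjugating enzyme of mitosis, 8.74-fold. Of 37 extracellular matrix genes, 18 rose over all genes tested and 24 adjusted over the list alone, with a median of 1.73 (camera adjusted p = 6.96e-12; adjusted p = 0.561 with an estimated correlation). The collagen gene Col3a1 rose 4.92-fold (SE 0.267 on the log2 scale, adjusted p = 0.0114), the microfibril gene Fbn1 5.01-fold and Loxl2, a lysyl oxidase-like enzyme, 3.32-fold. Col8a1 rose 10.3-fold and the collagen cross-linking enzyme gene Lox 8.76-fold. The mean log2 level of the matrix list was 2.00 above the 8-library mean in WT TAC replicate 1 and 0.29 above it in WT TAC replicate 2. In that replicate 1 library, immunoglobulin genes were at 624 CPM (reads scaled to the library total), against 19.0 to 51.8 in the other 7 libraries. Top2a, Ube2c, Col3a1, Fbn1 and Loxl2 passed whichever library was left out. Without WT sham replicate 2, Cks2, Rrm2, Col8a1 and Lox did not pass; Rrm2, Col8a1 and Lox also failed without WT sham replicate 1, Col8a1 and Lox without WT TAC replicate 1, and Rrm2 and Lox without either Cko sham library (adjusted p up to 0.124). Without WT TAC replicate 1 and without WT TAC replicate 2, in this order, the log2 fold change was 1.98 and 4.28 for Lox, 2.15 and 4.34 for Rrm2, 2.68 and 4.05 for Col8a1, 2.65 and 3.97 for Cks2, and 2.48 and 3.78 for Ube2c.

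Hypertrophy and fetal-programme genes rose as a list, with 13 of 21 higher and 1 lower over all genes tested, and 16 higher and 1 lower adjusted over the list alone. Their median log2 fold change was 1.58 (camera adjusted p = 1.3e-07; adjusted p = 0.561 with an estimated correlation). Ankrd1, a stretch-response gene of cardiac muscle, rose 6.63-fold (adjusted p = 0.0165), the skeletal actin gene Acta1 7.26-fold (adjusted p = 0.0313) and Nppb, which encodes brain natriuretic peptide, 4.06-fold (adjusted p = 0.0348). Rcan1, a target of calcineurin signalling, rose 3.34-fold (adjusted p = 0.0268). The slow myosin gene Myh7 had a log2 fold change of 2.29 (SE 0.638) that did not pass (adjusted p = 0.0545), at 266 FPKM in WT TAC replicate 1 and 56.7 in replicate 2. Myh6, the fast myosin of the adult mouse ventricle, fell 1.82-fold (adjusted p = 0.0458), and Myh7b was the list member that fell, by 3.41-fold. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a log2 fold change of -0.66 (adjusted p = 0.0678). The periostin gene Postn rose 7.17-fold (adjusted p = 0.0320) and Col1a1 4.12-fold (adjusted p = 0.0424), while Ctgf had a log2 fold change of 1.58 (adjusted p = 0.179). Piezo1 itself rose 1.91-fold (log2 fold change 0.93, SE 0.186, adjusted p = 0.0256). Without WT sham replicate 1, WT sham replicate 2 or WT TAC replicate 1, Ankrd1, Acta1, Nppb, Rcan1, Myh6, Postn, Col1a1 and Piezo1 did not pass (adjusted p up to 0.182), and without the latter 2 of these Myh7b did not. Without WT TAC replicate 2, Acta1 and Piezo1 did not pass, while Myh7 (adjusted p = 0.00605), Ctgf (0.0335) and Atp2a2 (0.0374) did, and without either Cko sham library Nppb, Rcan1, Myh6, Postn, Col1a1 and Piezo1 did not pass. Over these 6 fits the adjusted p of Piezo1 ran from 0.0538 to 0.103, and it was 0.0698 with no filter on low values and 0.058 with only the 4 wild-type libraries in the fit. The log2 fold change without WT TAC replicate 1 and without replicate 2 was 1.18 and 3.40 for Myh7, 0.431 and 2.74 for Ctgf, 1.89 and 3.79 for Postn, and 1.30 and 2.79 for Col1a1. Without WT sham replicates 1 and 2 it was 2.20 and 3.52 for Acta1, and 3.51 and 2.18 for Postn.

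Macrophage markers rose as a list (5 of 20 higher, 12 adjusted over the list alone; camera adjusted p = 0.000175), as did chemokines and cytokines (4 of 23, and 4 adjusted over the list alone; 0.00835), TGF-beta signalling genes (1 of 21, and 1 adjusted over the list alone; 0.000782) and YAP/TAZ and SRF targets (3 of 22, 4 adjusted over the list alone; 0.00871). Each of these 4 lists had an adjusted p = 0.561 with an estimated correlation. The macrophage genes Cx3cr1 and Adgre1 rose 2.84-fold and 2.93-fold, the chemokine gene Cxcl10 3.47-fold, the receptor gene Tgfbr2 1.88-fold and Fstl1 3.98-fold. Without WT sham replicate 2 none of these 5 genes passed, and without WT TAC replicate 1 only Fstl1 did; without WT sham replicate 1 Adgre1 and Cxcl10 failed, without either Cko sham library Cx3cr1 and Adgre1, and without WT TAC replicate 2 Adgre1 (adjusted p up to 0.140). The YAP/TAZ and SRF list did not pass without WT sham replicate 1 (adjusted p = 0.155) and the chemokine list without WT TAC replicate 2 (adjusted p = 0.0688).

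Of 37 nuclear genes of oxidative phosphorylation and the citric acid cycle, 24 fell (28 adjusted over the list alone), with a median log2 fold change of -0.83 (camera adjusted p = 1.24e-12; adjusted p = 0.561 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, fell 2.33-fold and Ndufa5, a subunit of complex I, 2.63-fold. Of 33 genes of fatty acid uptake and oxidation, 12 fell (21 lower and 1 higher adjusted over the list alone), with a median of -0.64 (camera adjusted p = 8.11e-08; adjusted p = 0.561 with an estimated correlation). The fatty acid transporter gene Slc27a1 fell 2.57-fold (adjusted p = 0.00573) and Ech1 3.09-fold. Of 23 channel genes, 6 fell (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0203; adjusted p = 0.561 with an estimated correlation), among them the potassium channel genes Kcnip2, by 2.55-fold, and Kcnv2, by 4.03-fold. Of 23 sarcomere genes, 4 fell (6 adjusted over the list alone; camera adjusted p = 0.0203; adjusted p = 0.572 with an estimated correlation), with the troponin genes Tnni3 down 2.96-fold and Tnnt2 2.01-fold. By the naming rule, the largest falls of single genes were Gapdh at 46.4-fold, Lgals4 at 11.8-fold, Mir208b at 9.86-fold, Inmt at 9.15-fold, Ces1d at 8.12-fold and Cytl1 at 6.34-fold. Mir208b lies inside Myh7 on the same strand, a gene with a positive value in this comparison, and Gapdh was high in the 2 WT sham libraries alone. Slc27a1, Kcnv2, Gapdh and Ces1d passed whichever library was left out. Without WT TAC replicate 1 none of the other genes named here passed, and without WT sham replicate 2 only Cytl1 among them did; without WT sham replicate 1 Ndufa5, Ech1, Tnni3, Tnnt2 and Mir208b failed, and without either Cko sham library Tnni3 and Tnnt2 (adjusted p up to 0.112). Without WT TAC replicates 1 and 2 the log2 fold change was -2.37 and -3.67 for Ces1d, and -2.70 and -3.90 for Mir208b. The channel list did not pass without WT sham replicate 1 (adjusted p = 0.109) and the sarcomere list without WT sham replicate 2 (adjusted p = 0.0777).

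For this comparison in wild type, the count of 1842 genes was 74 without WT TAC replicate 1, 185 without WT sham replicate 2, 494 without WT sham replicate 1, and 425 and 424 without Cko sham replicates 1 and 2; it was 247 with no filter on low values, 272 with only the 4 wild-type libraries in the fit, 703 with an absolute log2 fold change of at least 1, 1175 with a clock gene covariate and 1 without both WT sham replicate 1 and WT TAC replicate 1. Of the 49 named genes that passed, 11 passed whichever library was left out, and 17 lists in place of 11 passed without WT sham replicate 2.

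In hearts labelled Piezo1-Cko, TAC against sham asked the same question. Matrix and cell cycle genes rose as lists (each adjusted p = 0.449 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735, overlapping Syn1), rose 38.6-fold from 3.64 ± 0.0499 to 180 ± 117 FPKM (SD, n = 2; log2 fold change 5.27, SE 0.406, adjusted p = 0.0230). The tenascin C gene Tnc rose 15.6-fold, Serpina3n 8.51-fold and Aldh1a2, an enzyme of retinoic acid synthesis, 7.48-fold. By the naming rule, the largest falls were Inmt at 12.8-fold, Penk at 4.37-fold, Cyp1a1 at 3.90-fold, Tbc1d10c at 3.31-fold, Kcnv2 at 3.22-fold and Ttll1 at 3.05-fold. In all, 132 genes were higher and 76 lower, and 3036 had an unadjusted p under 0.05. Without either Cko sham library none of the 28 named genes that passed kept its call (adjusted p up to 0.293), and without Cko TAC replicate 1 24 of them lost it, all but Timp1, Tnc, Inmt and Mki67. Without either WT sham library 10 of the 28 lost it, and without Cko TAC replicate 2 6 did. Without Cko TAC replicates 1 and 2 the log2 fold change was 4.55 and 5.99 for Timp1, 3.36 and 4.56 for Tnc, and -4.35 and -3.01 for Inmt.

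Of the 26 cell cycle genes, 13 rose over all genes tested and 24 adjusted over the list alone (median 1.58, camera adjusted p = 8.53e-22; adjusted p = 0.449 with an estimated correlation). Mki67 rose 4.52-fold (adjusted p = 0.0230) and Top2a 4.31-fold. Of the 37 matrix genes, 8 rose over all genes tested and 22 adjusted over the list alone (median 1.64, camera adjusted p = 4.72e-14; adjusted p = 0.449 with an estimated correlation), with Loxl2 up 4.77-fold and Col3a1 4.47-fold (adjusted p = 0.0296). In the hypertrophy list (median 1.24, camera adjusted p = 2.21e-08; adjusted p = 0.449 with an estimated correlation), Ankrd1 rose 5.19-fold (adjusted p = 0.0453) and Myh7b fell 2.81-fold. The other 19 of its 21 genes did not pass over all genes tested; adjusted over the list alone, 12 were higher and 1 lower. Log2 fold changes that did not pass were 2.62 for Nppa (adjusted p = 0.0535), 3.40 for Acta1 (adjusted p = 0.0514), 3.19 for Postn (adjusted p = 0.0547), 2.07 for Col1a1 (adjusted p = 0.0805) and 2.14 for Ctgf (adjusted p = 0.153). Values were smaller for Nppb at 0.73 (adjusted p = 0.407), Myh7 at 0.65 (adjusted p = 0.602) and Rcan1 at 0.51 (adjusted p = 0.448). Myh6 had a log2 fold change of -0.60 (adjusted p = 0.180), Atp2a2 of -0.57 (adjusted p = 0.158) and Piezo1 of 0.32 (adjusted p = 0.359). Each gene named here as risen or fallen lost its call without either Cko sham library (adjusted p up to 0.293). Without either WT TAC library Nppa, Acta1, Postn and Col1a1 passed (adjusted p 0.0125 to 0.0486). The log2 fold change of Acta1 was 2.47 without Cko sham replicate 1 and 4.32 without Cko sham replicate 2.

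Macrophage markers rose as a list (4 of 20 higher, 14 adjusted over the list alone; camera adjusted p = 1.46e-10; adjusted p = 0.449 with an estimated correlation): Cd68 rose 3.12-fold, and the complement genes C1qb and C1qc 1.91-fold and 1.71-fold. Chemokines and cytokines (1 of 23 higher, 4 adjusted over the list alone; camera adjusted p = 1.2e-05; adjusted p = 0.449 with an estimated correlation) rose too, with Cxcl10 up 4.85-fold. YAP/TAZ and SRF targets (2 of 22 higher; 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0083; adjusted p = 0.50 with an estimated correlation) did as well, with Fstl1 up 3.84-fold. TGF-beta signalling (camera adjusted p = 0.0049; adjusted p = 0.560 with an estimated correlation), immediate early (0.00196; adjusted p = 0.568 with an estimated correlation) and interferon-stimulated genes (0.0105; adjusted p = 0.774 with an estimated correlation) rose as lists. No member of these passed over all genes tested, and 0, 1 and 0 did adjusted over the list alone.

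Fatty acid genes (2 of 33 lower, 15 adjusted over the list alone; camera adjusted p = 2.52e-08; adjusted p = 0.484 with an estimated correlation), channels (3 of 23 lower, 6 adjusted over the list alone; 0.00339; adjusted p = 0.449 with an estimated correlation) and glycolysis genes (1 of 24 lower; 4 lower and 1 higher adjusted over the list alone; 0.0281; adjusted p = 0.449 with an estimated correlation) fell as lists. Slc27a1 fell 1.73-fold, Kcnip2 2.83-fold and Pfkm 1.67-fold. Oxidative phosphorylation genes fell as a list with 31 of 37 lower adjusted over the list alone and 0 over all genes tested (camera adjusted p = 4.72e-14; adjusted p = 0.449 with an estimated correlation). Sarcomere genes (camera adjusted p = 0.0083; adjusted p = 0.530 with an estimated correlation) and mitochondrially encoded genes (0.0285; adjusted p = 0.724 with an estimated correlation) fell with 0 members passing over all genes tested and 0 adjusted over the list alone. Glycolysis genes did not pass as a list without Cko sham replicate 2 or Cko TAC replicate 2, mitochondrially encoded genes without Cko sham replicate 1 or Cko TAC replicate 1, and sarcomere genes without Cko sham replicate 2 or Cko TAC replicate 1 (adjusted p up to 0.212). In the same way immediate early genes failed without Cko sham replicate 2 or Cko TAC replicate 1, interferon-stimulated genes without Cko TAC replicate 2, and TGF-beta signalling genes and YAP/TAZ and SRF targets without Cko TAC replicate 1 (adjusted p up to 0.168). The count of 208 genes was 0 without either Cko sham library, 6 without Cko TAC replicate 1, 94 and 95 without WT sham replicates 2 and 1, 357 and 362 without WT TAC replicates 1 and 2, and 378 without Cko TAC replicate 2; it was 0 with no filter on low values and 0 with a clock gene covariate, and 353 to 397 under 5 other alternatives.

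**Figure D2:**
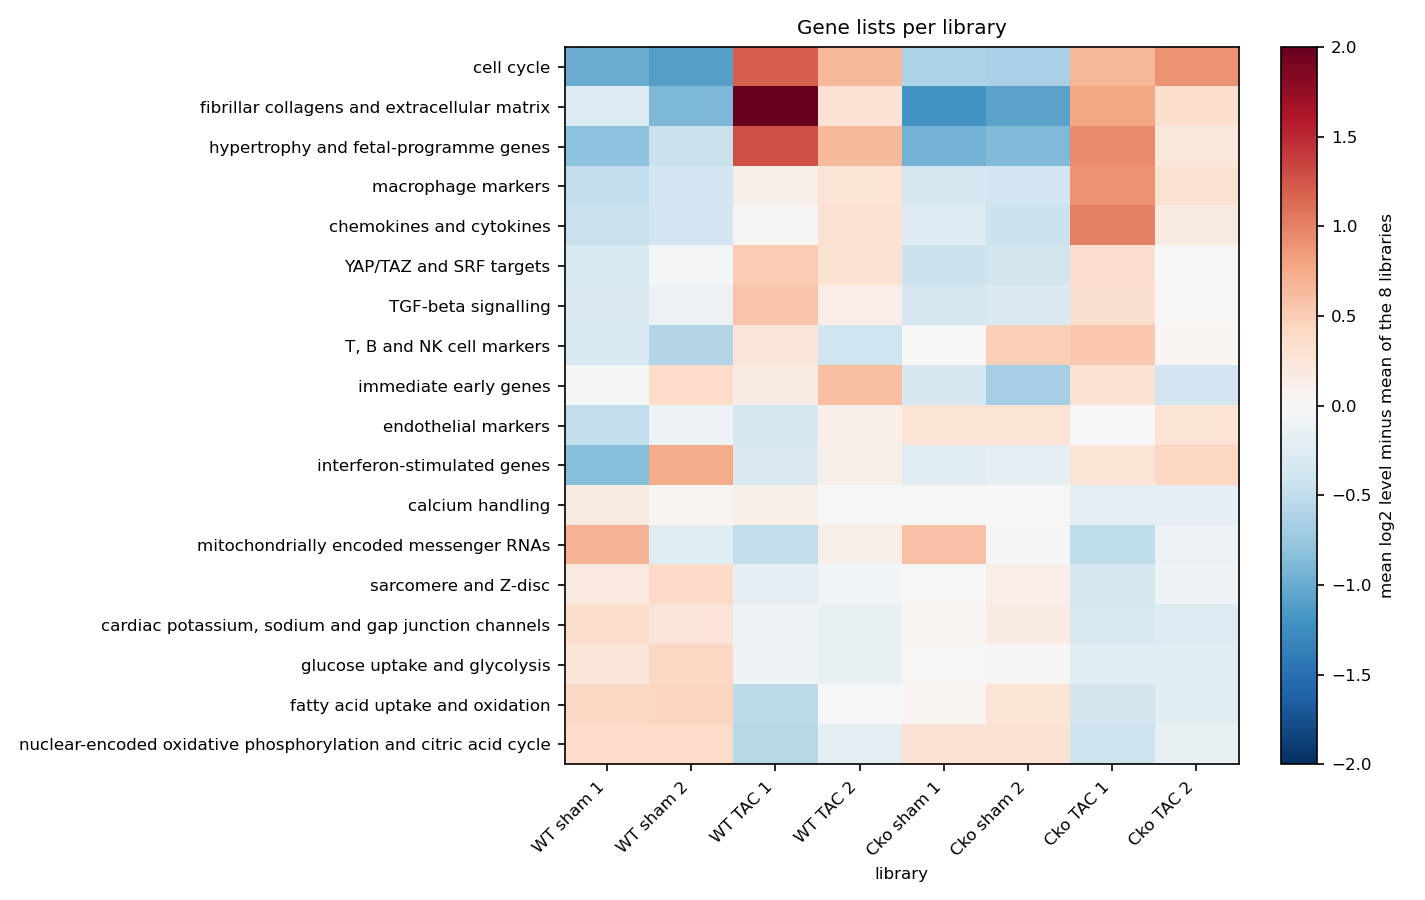
Mean log2(FPKM + 0.5) of each gene list that passed in at least 1 comparison, as the difference from the mean of the 8 libraries (colour, log2 units), for each library (columns). Cell cycle and hypertrophy genes were above the mean in all 4 TAC libraries and below it in all 4 sham libraries; matrix genes reached 2.00 in WT TAC replicate 1.

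The responses to TAC were then set side by side; they share no library. Of the 1842 genes that passed in wild type, 1779 (96.6%, exact 95% interval 95.7 to 97.4, which treats genes as independent) had the same sign in Piezo1-Cko. All 208 genes that passed in Piezo1-Cko had the same sign in wild type (exact 95% interval 98.2 to 100%). Among genes higher in both, 109 were shared, against 7.35 for independent lists, and among genes lower in both, 62 against 5.82. The lists are not independent, since both comparisons used 1 estimate of the spread per gene from all 8 libraries. Of the tested genes, 0 passed in opposite directions. Genes higher in wild type had a median log2 fold change of 0.94 there and 0.61 in Piezo1-Cko, and genes lower in wild type had medians of -0.86 and -0.54. Read the other way, genes higher in Piezo1-Cko had a median of 1.36 there and 1.26 in wild type, and those lower had -1.11 and -0.94. Values are inflated by selection in the genotype where genes passed. Across the 13928 genes, which are not independent replicates, Pearson's r of the fold changes was 0.732 and Spearman's rho 0.708.

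**Figure D3:**
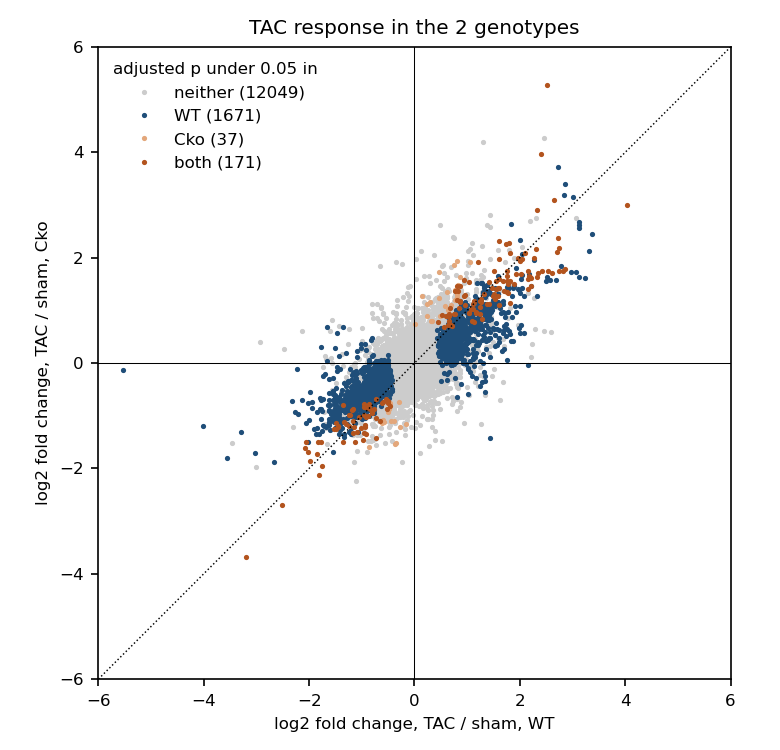
Log2 fold change of TAC against sham for each of 13928 tested genes in wild type (horizontal) and in Piezo1-Cko (vertical), with the dotted line marking equal values and colours marking the genotype in which the adjusted p was under 0.05. The 171 genes that passed in both have the same sign in both genotypes, and the point farthest left is Gapdh.

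Genotypes were compared under sham to ask what differed before pressure overload. Gapdh, a glycolytic enzyme gene (chromosome 6, 125161715 to 125166467, overlapping Iffo1), was 32.7-fold lower in the libraries labelled Piezo1-Cko, at 2.58 ± 0.381 FPKM against 102 ± 29.0 (SD, n = 2; log2 fold change -5.03, SE 0.202, adjusted p = 0.000227). Aplnr, the apelin receptor gene and an endothelial marker (chromosome 2, 85136225 to 85139923), was 3.88-fold higher, at 46.8 and 41.3 FPKM against 10.4 and 11.6 (SE 0.172 on the log2 scale, adjusted p = 0.0240). In all, 3 of 13928 genes passed and 1069 had an unadjusted p under 0.05. The pseudogene Gm49326 (log2 fold change 1.75, adjusted p = 0.0215) was named after its values were seen; reads of a pseudogene can be shared with its parent. In each of these 3 genes the WT sham libraries also stood apart from the WT TAC libraries. Aplnr lost its call without either WT sham, either WT TAC or either Cko sham library (adjusted p up to 0.296), while Gapdh passed whichever library was left out. The count was 1 without either WT TAC or either Cko sham library and with no filter on low values.

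Endothelial markers were higher as a list, with 17 of 18 positive and a median log2 fold change of 0.53; 1 passed over all genes tested and 4 adjusted over the list alone (camera adjusted p = 3.01e-10; adjusted p = 0.492 with an estimated correlation). Besides Aplnr, Cdh5 (0.95, adjusted p = 0.414) and the receptor gene Kdr (0.92, adjusted p = 0.398) had positive values that did not pass. Cell cycle genes (24 of 26 positive, median 0.41, camera adjusted p = 4.98e-08) and the 5 measured lymphocyte markers of 17 listed (all 5 positive, median 0.70, 0.00206) were also higher as lists, with 0 and 1 members passing adjusted over the list alone and 0 over all genes tested. Each had an adjusted p = 0.492 with an estimated correlation. Immediate early genes were lower as a list, with 23 of 24 negative, a median of -0.55 and 2 lower adjusted over the list alone (camera adjusted p = 1.2e-09; adjusted p = 0.492 with an estimated correlation). Among them Atf3 was at -1.32 (adjusted p = 0.375). Fatty acid genes (median -0.19, camera adjusted p = 0.000266; adjusted p = 0.797 with an estimated correlation), sarcomere genes (-0.21, 0.000666; adjusted p = 0.492 with an estimated correlation), matrix genes (-0.42, 0.00469; adjusted p = 0.863 with an estimated correlation) and channel genes (-0.22, 0.0341; adjusted p = 0.492 with an estimated correlation) were lower as lists. No member of these 4 passed, either over all genes tested or adjusted over the list alone. Thbs1, an extracellular matrix glycoprotein gene, was at -2.17 (adjusted p = 0.489). The glycolysis list (median -0.10, camera adjusted p = 0.0180; adjusted p = 0.492 with an estimated correlation) passed with Gapdh in it, the 1 member that passed over all genes tested and adjusted over the list alone, and had a camera adjusted p of 0.150 without Gapdh. WT sham replicate 1 held transcripts typical of atrial muscle, with Myl7 at 394 FPKM against at most 0.443 in the other 7 libraries. Channel and matrix genes did not pass as lists without WT sham replicate 1 or Cko sham replicate 1, fatty acid genes without Cko sham replicate 1, and lymphocyte, sarcomere and glycolysis genes without WT sham replicate 2 (adjusted p up to 0.464).

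Genotypes were compared under TAC to ask whether the overloaded hearts differed. By limma 0 genes passed, with 1269 genes at an unadjusted p under 0.05, and limma-voom on the recovered reads gave 0 as well. The 3 genes with the smallest p, none of them passing, were Retreg1 at a log2 fold change of -0.91, Grrp1 at 0.95 and Gstp2 at 1.22 (adjusted p = 0.449 for each). Macrophage markers were higher as a list in the libraries labelled Piezo1-Cko, with 17 of 20 positive and a median of 0.49 (camera adjusted p = 0.000254; adjusted p = 0.752 with an estimated correlation); Cd68 was at 0.99 (adjusted p = 0.481). Chemokines and cytokines (19 of 23 positive, median 0.35, camera adjusted p = 0.00641; adjusted p = 0.752 with an estimated correlation), interferon-stimulated genes (23 of 23, 0.42, 0.00713; adjusted p = 0.777 with an estimated correlation) and endothelial markers (15 of 18, 0.27, 0.0087; adjusted p = 0.752 with an estimated correlation) were higher too. Lower as lists were immediate early genes (19 of 24 negative, median -0.43, camera adjusted p = 0.00164), matrix genes (32 of 37, -0.50, 0.00327), hypertrophy genes (13 of 21, -0.49, 0.017), sarcomere genes (14 of 23, -0.12, 0.0465) and YAP/TAZ and SRF targets (15 of 22, -0.12, 0.0465). Each of these 5 had an adjusted p = 0.752 with an estimated correlation. Calcium handling genes were lower as well (18 of 24 negative, median -0.18, camera adjusted p = 0.00641; adjusted p = 0.685 with an estimated correlation). Over all genes tested 0 members of these 10 lists passed; adjusted over the list alone, 1 sarcomere gene and 2 YAP/TAZ and SRF targets were lower. Myh7 had a log2 fold change of -2.38 (adjusted p = 0.505), which was -1.27 without WT TAC replicate 1 and -3.49 without WT TAC replicate 2 (adjusted p = 0.0362), and Rcan1 of -1.41 (adjusted p = 0.481). The libraries compared also differed in clock genes: the index of circadian clock genes was 0.00 and 2.01 in WT TAC and 3.18 and 3.53 in Cko TAC, so genotype and clock gene levels are not separated here. Ryr2, the calcium release channel gene, was at -0.57 (adjusted p = 0.481) and Tead1, a partner of YAP, at -0.79 (adjusted p = 0.449).

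Under TAC, 18 genes passed between the genotypes without WT TAC replicate 2, 2 higher and 16 lower, and 1 passed without either WT sham library and with only the 4 libraries compared. Each of the 10 lists failed without at least 1 library: macrophage, chemokine and calcium handling genes without Cko TAC replicate 1, matrix genes without Cko TAC replicate 2 (adjusted p = 0.227), and hypertrophy, interferon-stimulated and endothelial genes without WT TAC replicate 1 or Cko TAC replicate 2. Immediate early genes failed without WT TAC replicate 2 or Cko TAC replicate 2, sarcomere genes without WT TAC replicate 2, Cko TAC replicate 1 or either Cko sham library, and YAP/TAZ and SRF targets without any library but Cko TAC replicate 1 (adjusted p up to 0.988 over the 10 lists). The lower matrix list rested on WT TAC replicate 1: without it the matrix genes were higher in Piezo1-Cko as a list, with a median of 0.251 (adjusted p = 0.0294). The mean log2 level of the list was 2.00 in that library and 0.29, 0.77 and 0.36 in the other 3 TAC libraries. Without Cko TAC replicate 1 the direction of the chemokine list turned as well (adjusted p = 0.988). The median turned to -0.00665 for endothelial markers without WT TAC replicate 1, and to 0.00219 and 0.0129 for sarcomere genes without WT TAC replicate 2 and Cko TAC replicate 1.

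The interaction asked directly whether the TAC response differed between the genotypes. The clock gene index was 0.18 and 3.14 in WT sham and 0.00 and 2.01 in WT TAC. It was -0.11 and 3.06 in Cko sham and 3.18 and 3.53 in Cko TAC. Clock gene levels are thus not separated from a difference of the responses. With the index as a covariate 1 gene passed. Gapdh was the only gene to pass by limma, with a log2 difference of 5.40 (SE 0.286, adjusted p = 0.00176), and 664 genes had an unadjusted p under 0.05. The pseudogene-type or predicted genes Gm49326 (adjusted p = 0.314) and Gm42778 (adjusted p = 0.332) had the next smallest p. Piezo1 had a log2 difference of -0.61 (SE 0.262, adjusted p = 0.911). Differences between the genotypes' responses in Nppb, Myh7 and Rcan1 did not pass either. Values of cell cycle genes were lower as a list (25 of 26 negative, median -0.51, camera adjusted p = 7.34e-07; adjusted p = 0.862 with an estimated correlation). Endothelial markers were lower too (15 of 18 negative, median -0.31, camera adjusted p = 0.00787; adjusted p = 0.950 with an estimated correlation). Macrophage markers (16 of 20 positive, median 0.31, camera adjusted p = 0.0269; adjusted p = 0.950 with an estimated correlation) and interferon-stimulated genes (21 of 23 positive, median 0.62, 0.0122; adjusted p = 0.950 with an estimated correlation) were higher. Over all genes tested 0 members of these 4 lists passed; 1 endothelial marker was lower adjusted over the list alone. Ccnb1 had a log2 difference of -1.10, Kdr of -1.01, Cd68 of 0.78 and Isg15 of 1.23, each with an adjusted p of 0.911. Isg15 was at 13.5 FPKM in WT sham replicate 1 and 55.8 in WT sham replicate 2, and its log2 difference was 2.23 without the former and 0.22 without the latter. Cell cycle genes passed as a list whichever library was left out; the endothelial list failed without WT sham replicate 1, WT TAC replicate 2 or Cko TAC replicate 1, the macrophage list without WT TAC replicate 1, Cko sham replicate 2 or Cko TAC replicate 1, and the interferon list without WT TAC replicate 1 or Cko TAC replicate 2 (adjusted p up to 0.908). Without WT sham replicate 2 the interferon list turned, with a median log2 difference of -0.204 (adjusted p = 0.0145), and without Cko TAC replicate 1 the direction of the macrophage list turned (adjusted p = 0.908). In place of 4 lists, 14 passed without WT TAC replicate 2, 8 without WT sham replicate 2 and 7 without Cko sham replicate 1, and 3 genes in place of 1 passed without WT sham replicate 2 and 2 with no filter on low values.

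**Figure D4:**
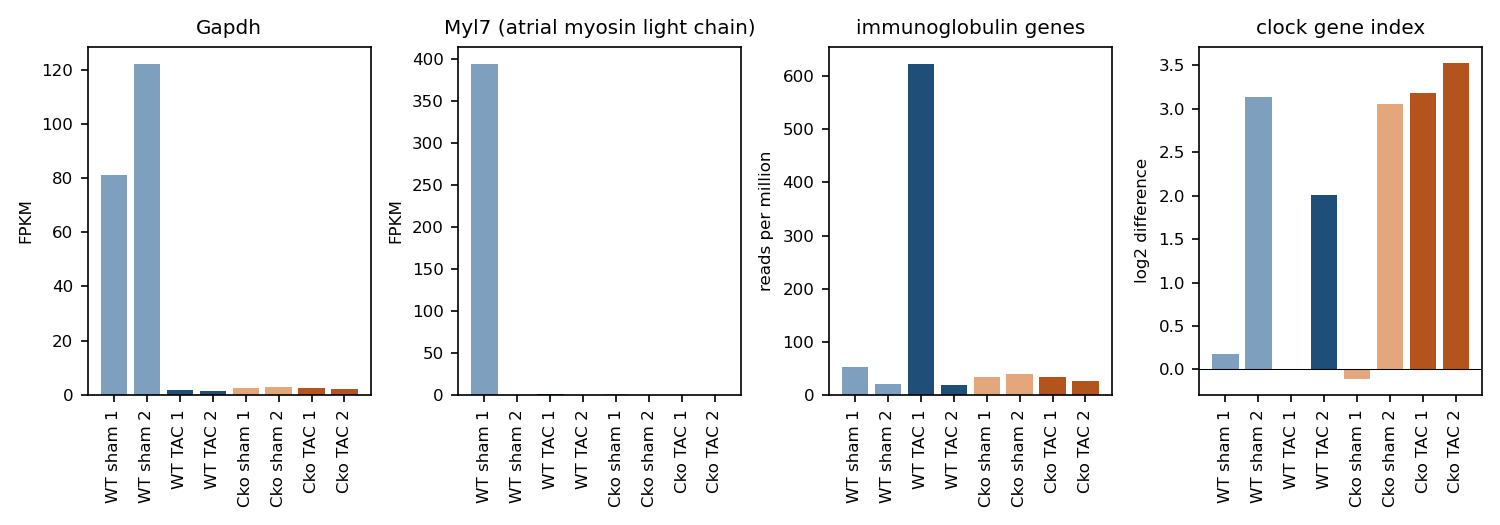
Values of each library (bars, horizontal axis): Gapdh and Myl7 in FPKM, all immunoglobulin genes in CPM, and an index of circadian clock genes (mean log2 level of Dbp, Nr1d1, Nr1d2, Tef, Per3, Ciart and Bhlhe41 minus that of Arntl, Npas2 and Clock). Gapdh was at 81.1 and 122 FPKM in the WT sham libraries and at most 2.85 in the others, Myl7 was at 394 in WT sham replicate 1, and immunoglobulin genes reached 624 CPM in WT TAC replicate 1.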

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

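The tests of explanations in this part were chosen after the results were seen, while the interaction test and the gene lists were planned. The interaction test set 5 results apart, the TAC responses of the genotypes differing in Gapdh and, with the preset correlation, in 4 gene lists, of which 0 passed with an estimated correlation.

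The log2 difference of the TAC responses of Gapdh was 5.40 (adjusted p = 0.00176), and it came from the WT sham libraries: 81.1 and 122 FPKM there, against 1.55 to 2.85 in the other 6. Gapdh has 90 pseudogene copies of at least 90% identity over at least 50% of the copy. A loss of shared reads outside WT sham that touches genes with many copies so defined as a class is argued against. The other 34 tested protein-coding genes with 10 or more copies had a median log2 difference of 0.177 (upper quartile 0.316), against 5.24 for Gapdh. These differences are WT sham minus the other 6 libraries. They cannot speak to such a loss at Gapdh alone, or at genes whose copies are closer than this threshold asks, and both stay open. Reads counted in the Gapdh copies were 499 and 615 in WT sham and 504 to 673 elsewhere. Reads counted at Gapdh were 4766 and 7166 in WT sham and 113 to 180 elsewhere. A fall of glycolysis genes as a group is argued against as well, since the other 23 had a median difference of 0.308 (upper quartile 0.476). A difference in handling or counting of the WT sham libraries that touches many genes cannot be told apart from the group itself: 7 tested genes set WT sham apart from all 6 other libraries by over 1 log2 unit, against at most 3 for another group. An effect of genotype and surgery on Gapdh alone stays open and untested, and a low value of this abundant glycolytic gene in 6 of 8 libraries asks for a look at the reads.

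More genes passed for TAC in wild type (1842) than in Piezo1-Cko (208). This may reflect a stronger profile in 1 WT TAC library. The order of the counts turned without WT TAC replicate 1 and held in the other 7 fits that leave out 1 of the 8 libraries. Each of these fits leaves 1 library in the group it was taken from, so the order of counts in them cannot settle this. The order also turned with only the 4 libraries compared in each fit (272 in wild type, 397 in Piezo1-Cko). Leaving out both WT sham replicate 1 and WT TAC replicate 1 leaves 1 library in each wild-type group, so that fit cannot weigh the order. Matrix genes were on average 2.58 log2 units above the sham mean of their genotype in WT TAC replicate 1 and 0.875 in replicate 2, against 1.90 and 1.48 in the Cko TAC libraries; cell cycle genes rose by 2.23 and 1.69 in WT TAC and by 1.30 and 1.53 in Cko TAC, but from a sham level that was higher in Piezo1-Cko (median 0.41), with a median of -0.11 between genotypes under TAC. A smaller TAC response with the Piezo1-Cko genotype cannot be told apart from this with 2 libraries a group. In the interaction test 0 genes other than Gapdh passed (664 had an unadjusted p under 0.05 by limma, and limma-voom passed 1 gene, Gapdh). Nor is it separated from clock gene levels, whose index was 3.18 and 3.53 in Cko TAC and -0.11 and 3.06 in Cko sham. With that index as a covariate 1175 genes passed for TAC in wild type and 0 in Piezo1-Cko.

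Atrial-type transcripts were high in WT sham replicate 1, with Myl7 at 394 FPKM, Sln at 43.6 and Myl4 at 40.4, against at most 0.443, 0 and 1.12 elsewhere. Dkk3, another gene read as atrial-type, was not high there alone. It was at 41.0 FPKM in that library and 25.2 in WT TAC replicate 1, against at most 2.13 in the rest. Atrial tissue in that library is a candidate source: of 6 further atrial-enriched genes (Kcnj3, Fgf12, Nr2f2, Tbx5, Gja5, Angpt1), 4 were highest there, Angpt1 by 3.95 FPKM against 3.94. But Nppa, abundant in atria, was at 112 FPKM against 116 in WT sham replicate 2, a ratio of 0.963, and Bmp10 was at 0, so atrial tissue cannot be told apart from another origin. No other origin of these transcripts was tested.

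The median log2 difference of the TAC responses was -0.51 for cell cycle genes, -0.31 for endothelial markers, 0.31 for macrophage markers and 0.62 for interferon-stimulated genes. The medians of Piezo1-Cko against wild type, under sham and then under TAC, were 0.41 and -0.11 for cell cycle genes, 0.53 and 0.27 for endothelial markers, 0.15 and 0.49 for macrophage markers, and -0.23 and 0.42 for interferon-stimulated genes. For the former 2 lists the median was thus larger in size under sham than under TAC, and that of endothelial markers was positive under both. Under TAC the libraries of the genotypes overlapped in endothelial markers. Their mean log2 level was 0.103 in WT TAC replicate 2 and 0.0128 in Cko TAC replicate 1, relative to the 8-library mean. Without WT TAC replicate 1 the median under TAC turned negative. Mean log2 levels of the interferon list were -0.85 and 0.74 in the WT sham libraries, relative to the 8-library mean, and without WT sham replicate 2 the median of this list was -0.204 (adjusted p = 0.0145), the other way.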

How the results depend on the processing

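The counts that follow were planned unless named as added after the data were seen, and their causes were not tested, except that no filter tests more genes and left-out libraries leave fewer samples. With no filter on low values, 247 genes passed for TAC in wild type, 0 for TAC in Piezo1-Cko, 1 between genotypes under sham and 2 for the interaction, and the share with the same sign was 87.9%. For TAC in Piezo1-Cko, limma-voom gave 390 genes, a mean CPM of at least 1 353, protein-coding genes alone 379 and the 4 libraries compared 397. The 4 libraries compared gave 272 for TAC in wild type and 1 between genotypes under TAC, and an absolute log2 fold change of at least 1 gave 703 for TAC in wild type. Read from the genes of Piezo1-Cko, 100% had the same sign. With an estimated correlation 0 lists passed in each of the 5 comparisons. By fry 4 lists passed for TAC in wild type, 4 in Piezo1-Cko, 1 between genotypes under sham, 1 under TAC and 0 for the interaction. Calpain and calcineurin genes were among them in the first 4 comparisons, though their median log2 fold changes were small, at 0.022, 0.084, -0.076 and 0.007 in this order. By camera this list passed in none of these (adjusted p 0.360 to 0.593). Channel and cell cycle genes passed for TAC in both genotypes, glycolysis genes in wild type and macrophage markers in Piezo1-Cko. The glycolysis list holds Gapdh and was not tested by fry without it. By camera it did not pass for TAC in wild type (adjusted p = 0.0956). Lists that did not pass by fry for TAC in wild type included matrix (adjusted p = 0.0802), oxidative phosphorylation (0.0549), hypertrophy (0.06), fatty acid (0.0735) and macrophage genes (0.0802). Keeping every row of a shared symbol, an added alternative, gave 3, 4, 1, 1 and 0 in this order. Also added, the clock gene index as a covariate gave 1175 genes for TAC in wild type and 0 in Piezo1-Cko. Leaving out both libraries that stand apart, added too, gave 1 gene for TAC in wild type, 397 in Piezo1-Cko and 1 between genotypes under TAC, 100% with the same sign (of that 1 gene), and Ctgf turned to -0.125 for TAC in wild type (adjusted p = 0.904). With 1 library left out, whose lone partner is assumed to vary like the other groups, counts ran from 74 to 2113 for TAC in wild type, 0 to 378 in Piezo1-Cko, 1 to 4 between genotypes under sham, 0 to 18 under TAC and 1 to 3 for the interaction. Lists ran from 10 to 17 for TAC in wild type and in Piezo1-Cko, 8 to 12 between genotypes under sham and under TAC, and 3 to 14 for the interaction. Of lists that passed with all libraries, 2 passed in the other direction: matrix genes between genotypes under TAC without WT TAC replicate 1 (median 0.251) and interferon-stimulated genes in the interaction without WT sham replicate 2 (median -0.204). The share with the same sign ran from 89.8% to 98.6%. For named genes, 1281 values with 1 library left out stayed on their side of the threshold, 251 lost and 28 gained a call; under other alternatives 2272 stayed, 199 lost, 37 gained and 1 changed sign. The values that stayed include those of genes that passed in neither fit, so they are not a count of calls kept. Gapdh kept its calls in all alternatives run. Libraries of different groups share only a replicate number in the labels. Correlations of the deviations of same-numbered libraries from their group means were positive in all 6 pairs of groups, from 0.0256 to 0.248, and over 0.1 in 2. The clock gene index was higher in replicate 2 than in replicate 1 of each group. It was 0.18 and 3.14 in WT sham, 0.00 and 2.01 in WT TAC, -0.11 and 3.06 in Cko sham, and 3.18 and 3.53 in Cko TAC. The number thus went with clock gene levels, least so in Cko TAC, and whether it marks anything else shared stays open. The replicate number as a block gave 2187, 236, 2, 0 and 1 genes in the order above. Other scalings moved no library by over 0.0083 log2 units. The DESeq2 Wald test and the edgeR fits were not run. At this depth a gene with 0 reads may have had up to 3 by counting error alone.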

Other observations

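The values and the test in this part were chosen after the results were seen, except for the gene lists, which were planned. An index of circadian clock genes (Dbp, Nr1d1, Nr1d2, Tef, Per3, Ciart and Bhlhe41 minus Arntl, Npas2 and Clock, mean log2 levels) was 0.18 and 3.14 in WT sham, 0.00 and 2.01 in WT TAC, -0.11 and 3.06 in Cko sham, and 3.18 and 3.53 in Cko TAC, replicate 1 first. Arntl, a core activator of the clock, was at 3.96 and 0.796 FPKM in WT sham, 4.02 and 1.39 in WT TAC, 3.89 and 1.04 in Cko sham, and 0.375 and 0.377 in Cko TAC. Adipocyte markers, 4 of 10 measured, had a mean log2 level 1.56 above the 8-library mean in WT sham replicate 1 and 0.07 above it in replicate 2. Granulocyte markers were at 0.65 and -0.62 in the Cko TAC libraries. Of the 87 tested genes within 3 Mb of Piezo1, 0 passed between genotypes under sham and 0 under TAC by limma. Over all 13928 tested genes 3 and 0 passed, so these counts do not speak against a change near Piezo1.

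By camera, 14 lists passed in no comparison. Their lowest adjusted p over the 5 comparisons was 0.0995 for the unfolded protein response, 0.10 for neurohumoral genes, 0.121 for mechanosensitive channels, 0.140 for smooth muscle and pericyte markers, 0.150 for adipocyte markers, 0.165 for fibroblast markers and for oxidative stress genes, and 0.181 for atrial markers. It was 0.182 for nerve and mesothelial markers, 0.232 for red blood cell markers, 0.268 for clock genes, 0.360 for calpain and calcineurin genes, 0.512 for neutrophil and mast cell markers, and 0.529 for lung, thymus and skeletal muscle markers.

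A set of 4 genes known to respond to glucocorticoids had negative values in sham hearts labelled Piezo1-Cko against wild type: log2 fold changes were -1.31 for Tsc22d3, -1.97 for Per1, -1.80 for Sik1 and -0.91 for Fkbp5, and the lowest adjusted p was 0.137. Lower glucocorticoid signalling or less handling stress in those hearts is a candidate explanation. A list of 16 further responsive genes, 15 of them measured, had a median of -0.741, with 13 of 15 negative (camera p = 4.76e-08 with the preset and 0.00431 with an estimated correlation), and 0 members passed on their own. Under TAC the median was -0.391 (p = 0.00908 with the preset and 0.0495 with an estimated correlation); these p-values are not adjusted and the TAC value is not read as a call. Tsc22d3 was at 48.8 and 41.7 FPKM in WT sham, 23.8 and 18.1 in WT TAC and 14.6 to 18.4 in the 4 Cko libraries, so the WT sham libraries also stood apart from WT TAC. The list was drawn up after the first 4 genes had been seen, on the same libraries, so this stays a hypothesis.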
